A study of Rattus norvegicus with 6 samples.

How the data were processed

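Genomic DNA of 6 samples of male rat hypothalamus taken at postnatal day 9 was sheared, ligated to methylated adapters, bisulfite converted and amplified by PCR, per the labels' protocols. The labels place 3 samples under augmented maternal care and 3 under control, and the replicate numbers come from the sample titles. The file headers call the same groups handled and not handled. BS-Seeker2, a bisulfite read aligner, and the rn6 build are named in the submitters' processing notes, and the version, the alignment settings, the treatment of duplicate reads and any filter are not given in the sources used here.

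The deposited files list each covered CpG with the methylated fraction and the read coverage that the authors computed, on 21 chromosomes. The fraction is rounded to hundredths, so methylated reads were recovered as the fraction times the coverage, rounded to a whole number. In each sample 100% of the lines gave a whole number of methylated reads within that rounding. At high coverage the rounding of the fraction no longer fixes the number of reads. The test called for by these values is one on methylated and unmethylated read calls, as designed. Positions are given here 1-based. The union over the 6 samples held 21720054 CpGs. Reads of PCR libraries are not independent molecules, and a fragment can cover several CpGs, so binomial error alone would be too small. The model below takes its spread from the replicates, but mostly over many windows together and little from the single window.

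Sequence variants against the reference matter for bisulfite data, because a C-to-T variant at a CpG reads as unmethylated. PCR and shearing also set how much CpG-rich DNA a library holds, which enters any level made from summed read calls. The share of read calls in CpG-dense DNA was measured. Sequence variants were not called, and only CpGs that resemble them by their methylation values were counted.

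Values with 1 number per sample were compared with an exact two-sided permutation test of the difference of group means over the 20 assignments of samples, whose smallest p is 0.1. The genome was divided into windows of 1 kb, and the number of CpGs of a window is the number listed in any sample. Windows with 10 or more read calls and 3 or more covered CpGs in every sample were tested, 1425026 in all. Methylated and unmethylated read calls were summed per window and sample and fitted with a quasi-binomial logistic model. Its Pearson dispersion was moderated over windows with limma squeezeVar and a trend on log mean coverage, followed by an F test and Benjamini-Hochberg adjustment, with calls at an adjusted p below 0.05. The moderation gave a prior of 63.5 degrees of freedom, so the spread between samples in a window itself weighed little. A window with a large spread of its own can therefore still get a very small p. Low-methylated windows are those at 10% or less.

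The windows named in the text were fixed by a rule before the data were examined: among called windows with all AMC samples on one side of all controls, the 10 with the smallest p in each direction. A further 9 windows called in the CpG-stratified test, 7 of them also called in the first model, were added after their values were seen and are said to be so. That test was itself added after the data were seen. It compares the groups within each CpG (Mantel-Haenszel) and sums over the window, takes its dispersion from the deviations of the samples within each group at the same CpGs, and uses the larger of the window's own and the moderated dispersion. The moderation gave a prior of 1e+06 degrees of freedom, so the F test treated either dispersion as known. Its p-values thus leave out the uncertainty of a dispersion estimated from few samples. The moderated dispersion alone was tried first, called 106 windows, and was replaced after windows with a large dispersion of their own were seen among them. The test was run on the 1407946 windows where that dispersion could be estimated from all samples. CpGs resembling sequence variants were found without regard to group, as those at 0 of 4 or more reads in one sample and at 70% or more of 4 or more reads in another, and made up 0.444% of all CpGs. This definition, the windows of 100 kb and the level over CpGs covered in all samples were likewise chosen after the data were seen.

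Both window tests were tested on simulated data with the real coverage, in which all samples shared each CpG's pooled level and 200 windows were changed in AMC against control. Over 1425026 windows the main model called 2 of 100 windows changed by 20 points and 8 of 100 changed by 30 points, and 19 unchanged windows, all lower in AMC. Over 1398746 windows the CpG-stratified test called 12 of 100 and 42 of 99 and no unchanged window. Simulated reads were drawn independently at each CpG, without the spread between samples or the shared fragments of real libraries. False calls can therefore be more numerous in the real data than these counts. The changed windows all had intermediate pooled levels, so changes in windows of low or high level were not simulated. The change was applied at each CpG and cut off at the lowest and highest possible level. Windows with CpGs near those bounds were therefore changed by less than the 20 or 30 points stated. Most simulated changes were missed, so many real ones of the sizes reached would not be seen at this depth. How many differences of a full 20 or 30 points would be missed was not measured.

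All 15 pairs of samples were compared for duplicated libraries. Over 120969 autosomal CpGs with 5 or more reads in every sample and pooled levels of 20% to 80%, squared differences between samples exceeded the sampling variance by factors of 1.04 to 1.11 in every pair, and window levels correlated with Pearson r of 0.922 to 0.945 across windows, which are not independent replicates. No pair was merged.

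The alternatives planned before the data were examined were each sample left out, the replicate number as a block, 30 or more read calls, 5 kb windows, clusters of CpGs, limma on log2((methylated + 1)/(unmethylated + 1)), no coverage trend, a dispersion of at least 1, the most variable CpG left out, CpGs above the 99.9th percentile of coverage left out, thinned read calls, a pooled Fisher test and, for genome-wide levels, CpGs with 5 or more reads in every sample with each counted once. Added after the data were seen were the larger dispersion, the CpG-stratified test with its own alternatives, and the levels over all CpGs covered in every sample. A genome annotation of rn6 was not used here, so promoters, gene bodies, gene lists and the genes at the named windows were not analysed here, and neither were the Y chromosome, mitochondrial DNA or unplaced sequence. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, pyarrow 21.0.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, data.table version 1.17.8 and arrow 21.0.0.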

Results

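Whole-genome bisulfite sequencing, which reads the methylation of cytosines after chemical conversion, was used to measure CpG methylation in the hypothalamus of male rats at postnatal day 9. The comparison set 3 samples from pups given augmented maternal care (AMC) against 3 control samples, and asked how CpG methylation differs in the hypothalamus after this early experience. Under augmented maternal care the pups receive more care from the dam, and the hypothalamus holds the neurons that drive the hormonal stress response. The AMC samples held 61598241, 71698027 and 83462414 CpG read calls, where a read call is 1 read at 1 CpG, and the control samples held 66299386, 86308923 and 91081635. The median coverage of a listed CpG was 3 reads in AMC samples 1 and 2 and control sample 1, and 4 reads in the other samples. Between 18192115 and 20151102 CpGs were listed per sample, on the 20 autosomes and the X chromosome, and the positions are those of the rn6 build. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples only.

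Of all CpG read calls on the autosomes, 76.6% ± 0.391 (SD, n = 3) were methylated in AMC samples and 79.7% ± 1.495 (SD, n = 3) in controls. The AMC samples stood at 76.9%, 76.2% and 76.8%, below each of the controls at 80.96%, 80.03% and 78.03%. The difference was -3.07 percentage points (exact two-sided permutation test, p = 0.1, the smallest p that 3 samples against 3 allow). The level measured this way depends on where in the genome the reads fell. At the 13518551 autosomal CpGs covered in all 6 samples, with each CpG counted once, the AMC samples averaged 78.1% ± 0.432 (SD, n = 3) and the controls 78.7% ± 0.665 (SD, n = 3), and the groups overlapped. That difference was -0.598 points (exact two-sided permutation test, p = 0.3). All 21 chromosomes had a lower mean in the AMC group under both measures, with differences from -0.636 to -0.516 points at the shared CpGs. The chromosomes were read in the same 6 samples, so they are not independent comparisons.

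**Figure D1:**
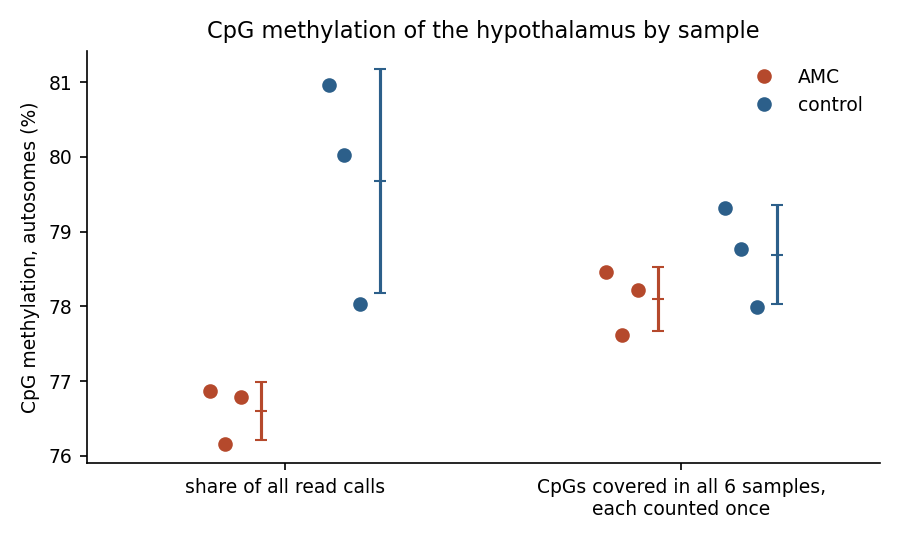
CpG methylation of the autosomes in percent for each of the 6 samples, measured as the share of all read calls (left) or over CpGs covered in all samples with each counted once (right); points are samples and bars are the group mean ± SD (n = 3). The 3 AMC samples lie between 76.2% and 76.9% by read calls, below all controls, and overlap them at the shared CpGs.

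Methylation followed CpG density closely in every sample, and the groups differed most in CpG-dense DNA when all read calls were used. Windows of 1 kb with under 10 CpGs were 82.6% ± 0.457 methylated in AMC samples and 83.2% ± 0.752 in controls (SD, n = 3). Windows with 10 to 29 CpGs stood at 80.4% ± 0.427 in AMC samples and 81.8% ± 1.13 in controls. Windows with 30 to 59 CpGs stood at 42.5% ± 1.16 in AMC samples and 51.7% ± 4.04 in controls, and those with 60 or more CpGs, the density of CpG islands, at 3.77% ± 0.197 and 6.204% ± 0.9199. All AMC samples lay below all controls in both dense classes (exact two-sided permutation test, p = 0.1, Benjamini-Hochberg adjusted p = 0.2 over the 4 classes), while adjusted p was 0.4 in windows with under 10 CpGs and 0.267 in those with 10 to 29. At the CpGs covered in all 6 samples, each counted once, the difference in windows with 30 to 59 CpGs was -0.655 points rather than -9.21, and in windows with 60 or more CpGs it was -0.265 points rather than -2.44. The densest class was still lower in every AMC sample than in every control at those shared CpGs, at 4.92% ± 0.0794 against 5.18% ± 0.156 (SD, n = 3; exact two-sided permutation test, p = 0.1).

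The libraries themselves differed in how much CpG-dense DNA they held. The labels give no batch of preparation or sequencing, so it is unknown whether one coincides with the groups, which bears on every difference by read calls given here. Windows with 60 or more CpGs took 2.91%, 2.83% and 2.70% of the read calls in the AMC samples and 1.22%, 1.28% and 1.79% in the controls (exact two-sided permutation test, p = 0.1). Windows with 30 to 59 CpGs took 5.97% ± 0.135 of the AMC read calls and 4.86% ± 0.413 of the control read calls (SD, n = 3). In the densest windows the coverage per CpG ranged from 2.88 to 3.63 reads over the AMC samples and from 1.30 to 2.63 reads over the controls.

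**Figure D2:**
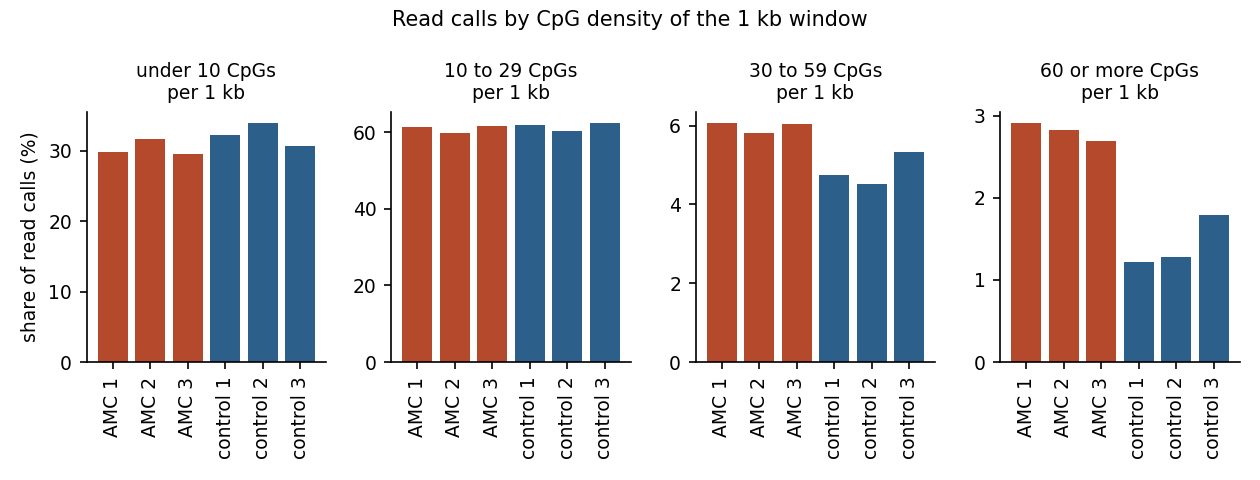
Share of each sample's CpG read calls, in percent, that fell in 1 kb windows of 4 CpG density classes; each bar is a sample, and each panel has its own axis from 0. Windows with 60 or more CpGs take 2.70% to 2.91% of the read calls in AMC samples and 1.22% to 1.79% in controls.

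The X chromosome, present in a single copy in males, was 78.0% ± 0.227 methylated by read calls in AMC samples and 80.4% ± 1.45 in controls (SD, n = 3), a difference of -2.38 points (exact two-sided permutation test, p = 0.1). At the X-linked CpGs covered in all samples the levels were 79.4% ± 0.479 and 79.9% ± 0.691, and the groups overlapped (exact two-sided permutation test, p = 0.4). Unmethylated regions were slightly more numerous in the AMC samples. Of the 1425026 windows tested, 1.76% ± 0.0312 were at 10% methylation or less in AMC samples and 1.55% ± 0.0441 in controls (SD, n = 3; exact two-sided permutation test, p = 0.1, all AMC samples above all controls). Window levels were also taken over the shared CpGs, in those tested windows that held 3 or more of them. The shares were then 1.76% ± 0.0217 and 1.70% ± 0.00748 (SD, n = 3), with all AMC samples still above all controls (exact two-sided permutation test, p = 0.1).

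Among single regions, 359 of the 1425026 windows of 1 kb were called different at a Benjamini-Hochberg adjusted p below 0.05 in the quasi-binomial model with limma-moderated dispersion. Methylation was lower in AMC samples in 342 of them and higher in 17. The median difference was -23.2 points in the windows called lower and 29.3 points in those called higher. The called windows were CpG-dense: 64.9% of them had 30 or more CpGs, against 2.65% of the windows tested, with 66 called of 7753 tested in the densest class and 19 of 583375 in the sparsest. In simulated reads with the real coverage, 14 of the 19 unchanged windows called also had 30 or more CpGs. The density of the called windows therefore does not set them apart from calls that coverage gives. At an unadjusted p below 0.001 with a difference of 10 points or more there were 3504 windows, 2943 lower and 561 higher in AMC samples. When both groups were compared at the same CpGs of each window, with a CpG-stratified test chosen after the data were seen, 11 windows were called, 10 lower and 1 higher. That test also takes the larger of 2 dispersions, which alone left 61 calls in the first model. At the same CpGs the median difference over the 354 of the 359 windows that could be tested was -3.46 points. No window was called by limma on log2 ratios (83978 of 1425026 tested at an unadjusted p under 0.05) or in the first model without the most variable CpG of each window (73302 of 1262235 tested). By chance alone a share of 0.05 of the windows tested would fall under that p. The count of 359 also fell to 55, 44, 118, 62 and 31 without AMC sample 1, 2 or 3 or control sample 1 or 2, in that order.

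The 10 windows with the smallest p among those lower in AMC samples fell into 2 kinds. In 4 of them the difference was of about the same size at the CpGs both groups covered. The window on chromosome 3 from 172375001 to 172376000, with 78 CpGs and 167 to 332 read calls per sample, was 45.4% ± 5.33 methylated in AMC samples and 71.2% ± 3.55 in controls (SD, n = 3; limma-moderated adjusted p = 9.66e-06), and its difference at the same CpGs was -24.7 points (CpG-stratified adjusted p = 8.22e-07). On chromosome 4 the window from 29796001 to 29797000 stood at 44.7% ± 6.34 against 69.99% ± 12.8, and the window on chromosome 14 from 92117001 to 92118000 at 50.0% ± 13.5 against 74.6% ± 6.13. Their differences at the same CpGs were -25.6 and -25.6 points, without passing the adjusted threshold of the CpG-stratified test. On chromosome 1 the window from 36750001 to 36751000 stood at 72.2% ± 7.10 in AMC samples and 86.8% ± 2.45 in controls. Its difference at the same CpGs was -12.8 points, and it was not called there either. It was the deepest of the named windows, with 63 CpGs and 1106 to 1657 read calls per sample. That depth is unusual where the median coverage of a listed CpG was 3 or 4 reads. The cause of the depth was not tested, nor whether the call holds without CpGs of very high coverage. In the other 6 windows the difference was much smaller, or turned, when both groups were compared at the same CpGs. On chromosome 7 the window from 116916001 to 116917000 was 43.3% ± 6.36 methylated by read calls in AMC samples and 82.2% ± 5.99 in controls, yet at the 14 CpGs covered in all samples the levels were 90.7% ± 1.96 and 88.9% ± 0.445. Likewise the window on chromosome 2 from 28003001 to 28004000 stood at 3.41% ± 1.71 against 28.6% ± 13.0 by read calls, with -0.980 points at the same CpGs. The windows on chromosome 5 from 62000001 to 62001000, chromosome 4 from 77612001 to 77613000, chromosome 1 from 216641001 to 216642000 and chromosome 16 from 82100001 to 82101000 had differences of -28.8, -35.8, -33.6 and -34.4 points by read calls and of 0.765, -1.13, -2.28 and -7.19 points at the same CpGs. Of the 4 windows that kept their difference, those on chromosomes 1 and 3 were called in the first model whichever sample was left out. That on chromosome 4 lost its call without AMC sample 3 (limma-moderated adjusted p = 0.0605) and that on chromosome 14 without AMC sample 2 (limma-moderated adjusted p = 0.0622). Among the other 6, 4 were called in that model whichever sample was left out. With limma on log2 ratios none of these 10 windows was called, the one on chromosome 3 included (limma adjusted p = 0.644).

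Of the 17 windows called higher in AMC samples, the 10 with the smallest p among those that separated the groups were examined. The window on chromosome 7 from 110495001 to 110496000, with 6 CpGs and 18 to 53 read calls per sample, was 95.6% ± 1.12 methylated in AMC samples and 62.6% ± 4.83 in controls (SD, n = 3; limma-moderated adjusted p = 0.0139), and was also called at the same CpGs with a difference of 32.5 points (CpG-stratified adjusted p = 0.0344). On chromosome 6 the window from 42037001 to 42038000 stood at 92.8% ± 0.495 against 76.6% ± 3.90, a difference of 16.1 points by read calls and 16.4 points at the same CpGs, where it was not called. That on chromosome 11 from 70899001 to 70900000 stood at 87.3% ± 4.25 against 63.9% ± 10.6, with 18.1 points at the same CpGs and no call there. A second window on chromosome 7, from 2457001 to 2458000, stood at 53.6% ± 11.3 against 20.9% ± 13.3, with 18.0 points at the same CpGs and no call there (CpG-stratified adjusted p = 0.332). The window on chromosome 4 from 179898001 to 179899000 had the smallest p in this direction, at 66.2% ± 14.6 against 36.9% ± 11.3 (limma-moderated adjusted p = 0.000849), and its difference at the same CpGs was 7.43 points. The other 5, on chromosomes 1, 2 and 10, had differences of 22.5 to 44.1 points by read calls and 2.52 to 23.6 points at the same CpGs. Adjusted p ranged up to 0.0389 in these 10 windows, and 6 of them, those on chromosomes 6 and 7 among them, were called in no setting with a sample left out. In those settings the difference ran from 31.0 to 35.7 points for the window on chromosome 7 from 110495001 and from 14.1 to 18.0 points for that on chromosome 6.

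**Figure D3:**
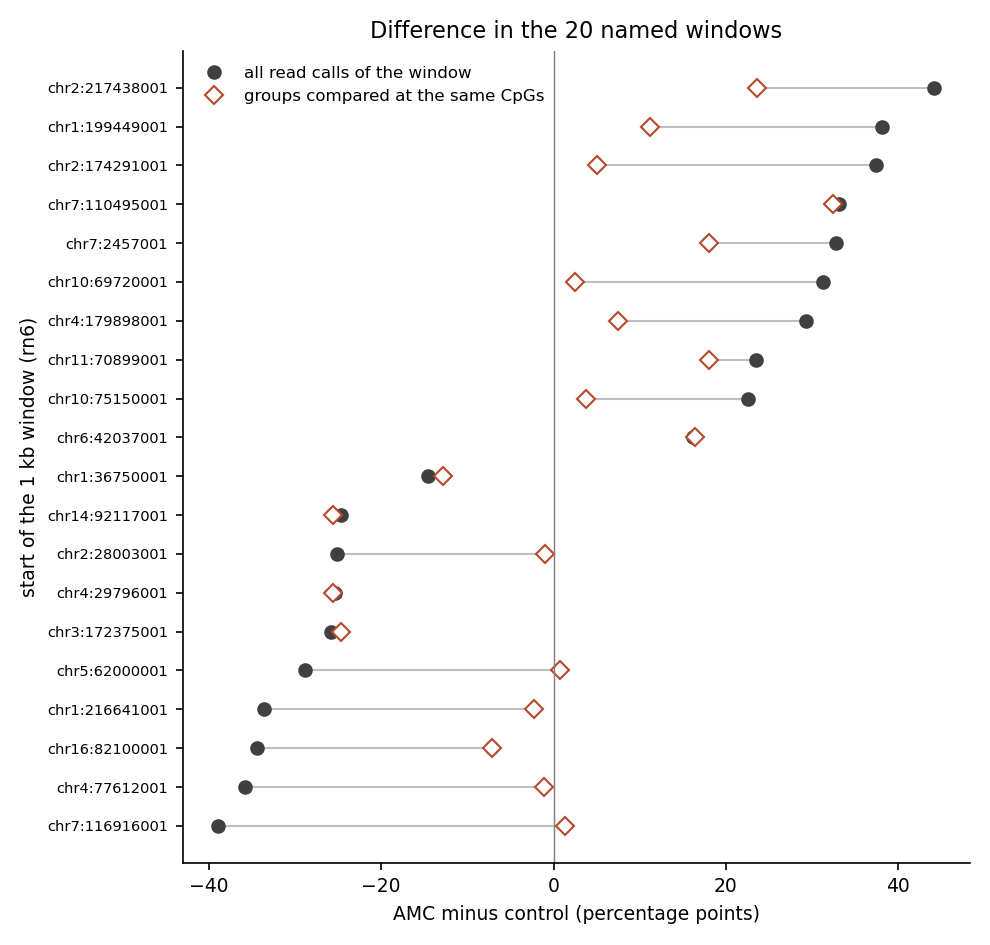
Difference in methylation, AMC minus control in percentage points, in the 20 windows named by the rule fixed before the data were examined; filled points use all read calls of the window and open diamonds compare the groups at the same CpGs. In 6 of the 10 windows lower in AMC samples the diamond lies between -7.19 and 1.37 points.

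The remaining windows called by the CpG-stratified test were picked after their values were seen. Besides the windows on chromosomes 3 and 7 given above, 9 windows were called at the same CpGs. All 9 were lower in AMC samples, and 7 were called in the first model too. The window on chromosome 1 from 222183001 to 222184000 was 13.0% ± 3.06 methylated in AMC samples and 35.7% ± 8.18 in controls by read calls (SD, n = 3), with a difference of -22.9 points at the same CpGs (CpG-stratified adjusted p = 0.000883). The window on chromosome 1 from 48176001 to 48177000, with 80 CpGs, stood at 6.09% ± 1.39 against 23.8% ± 3.28, with -14.6 points at the same CpGs (CpG-stratified adjusted p = 0.00937). On chromosome 9 the window from 10306001 to 10307000 stood at 40.7% ± 3.47 against 64.4% ± 4.22, with -22.3 points at the same CpGs, and on chromosome 20 that from 3814001 to 3815000 at 56.5% ± 5.21 against 74.6% ± 0.892, with -20.7 points. Chromosome 13 held 3 of the 9. The first, from 106428001 to 106429000, stood at 70.5% ± 6.62 against 95.8% ± 1.46, with -28.0 points at the same CpGs. The second, from 88722001 to 88723000, stood at 40.1% ± 4.41 against 67.1% ± 1.84, with -25.7 points at the same CpGs, and lost its call without CpGs resembling sequence variants (difference -24.4 points, adjusted p = 0.162). The other, from 41481001 to 41482000, stood at 56.1% ± 8.79 against 72.4% ± 6.34 and was not called in the first model (limma-moderated adjusted p = 0.326), while its difference at the same CpGs was -27.2 points. On chromosome 3 a further window, from 168323001 to 168324000, stood at 72.8% ± 3.36 against 86.6% ± 2.40, with -15.5 points at the same CpGs. It was not called in the first model (limma-moderated adjusted p = 0.223), and without the 3 of its 23 CpGs that resemble sequence variants its difference was -6.28 points and its call was lost. The largest difference of the 9 was in the window on chromosome 5 from 35396001 to 35397000, at 4.32% ± 3.93 in AMC samples and 62.4% ± 10.1 in controls, which rested on 5 CpGs and 11 to 33 read calls per sample, and could not be tested without its 1 such CpG. With a sample left out, 7 of the 9 kept their call in at most 1 setting, the window from 222183001 in 4 and that from 48176001 in 2, and with read calls thinned 8 of the 9 lost their call. Without control sample 1 the count of 11 fell to 1, and without AMC sample 3 it rose to 34.

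A longer stretch of chromosome 5, from 35200001 to 35700000, was lower in the AMC samples, and holds the window with the largest difference named above. It was picked after windows of 100 kb had been tested at the same CpGs, which called 4 of 27470, all of them here. The 100 kb from 35200001 stood at 69.4% ± 1.38 in AMC samples and 79.2% ± 3.05 in controls (SD, n = 3), that from 35300001 at 67.6% ± 0.463 and 79.3% ± 3.63, that from 35400001 at 71.7% ± 1.81 and 77.8% ± 0.878, and that from 35600001 at 70.7% ± 0.842 and 77.3% ± 1.64. Their CpG-stratified adjusted p was 0.0118, 0.042, 0.000979 and 0.000766. Over the whole stretch the difference at the same CpGs was -8.39 points, against -0.778 points in the 1 Mb on each side. The stretch also held many CpGs that were unmethylated in one sample and methylated in another, a pattern that a sequence variant gives too: they made up 6.18% of its CpGs with enough reads and 0.845% in the flanks. Leaving them out also removes CpGs that a loss of methylation would bring to 0. Without them the difference was -5.64 points and 1 of the 4 windows, that from 35300001, was called.

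**Figure D4:**
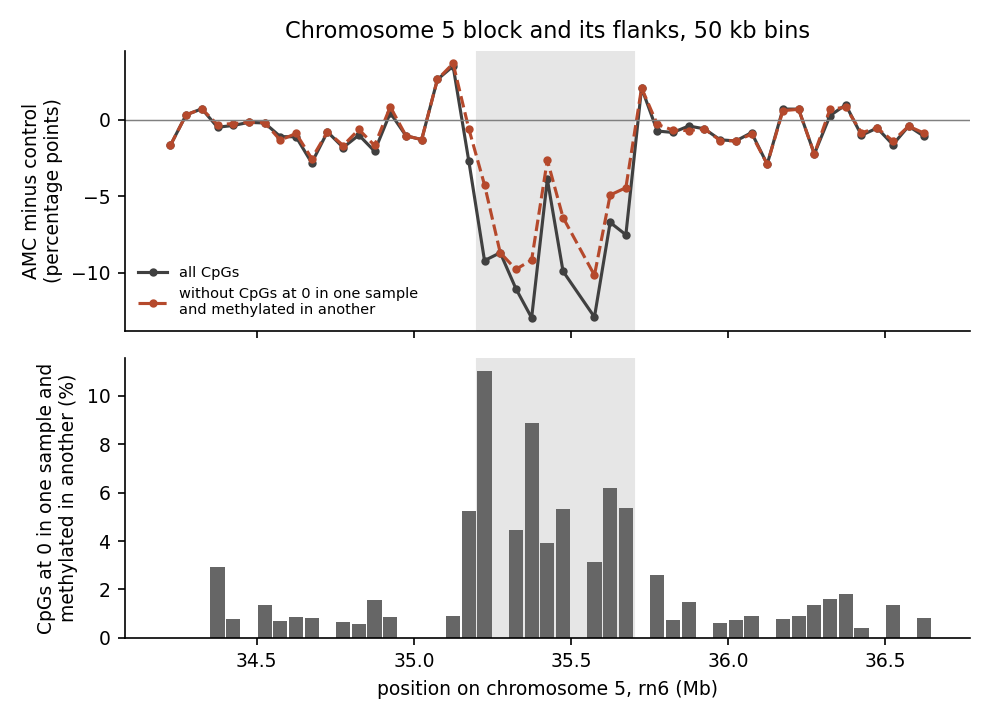
Difference in methylation at the same CpGs, AMC minus control in percentage points, in bins of 50 kb along chromosome 5 (top, in Mb of rn6; solid line all CpGs, dashed line without CpGs at 0 in one sample and methylated in another), and the percentage of such CpGs (bottom); the shaded stretch runs from 35200001 to 35700000. Over the shaded stretch the difference is -8.39 points, and in its flanks -0.778 points.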

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

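The levels over all CpGs covered in every sample, the larger dispersion, and the CpG-stratified test with all its settings were chosen after the data were seen, and the others before. The lower autosomal level kept its direction in all settings run, from -3.89 to -2.43 points with a sample left out, but was -0.577 points over CpGs with 5 or more reads in every sample and -0.598 points over CpGs covered in all samples. The X chromosome, the 4 density classes and the share of low-methylated windows also kept their direction in all settings run, though not their size: windows with under 10 CpGs differed by -0.948 to -0.198 points with a sample left out, those with 10 to 29 and 60 or more CpGs by -3.19 and -4.55 points in 5 kb windows, and the low-methylated share by 0.424 points with 30 or more read calls and 0.0618 points at the same CpGs. Since the smallest exact p is 0.1, no setting could pass the threshold, and the p-values say nothing of stability.

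The 359 windows called became 31 to 281 with a sample left out, 164 with 30 or more read calls, 172 with read calls thinned, 642 without the coverage trend, 6240 in 5 kb windows, 2169 in CpG clusters, 4546 with the pooled Fisher test, which ignores the spread between samples, 61 with the larger dispersion and 11 in the CpG-stratified test. limma on log2 ratios called 0, with 83978 of 1425026 windows at an unadjusted p under 0.05, and the main model without the most variable CpG called 0, with 73302 of 1262235. The 3504 windows at nominal p became 1924 to 3505 with a sample left out, 1706 with 30 or more read calls, 6290 in 5 kb windows, 1146 with limma on log2 ratios, 1399 without the most variable CpG, 2020 with the larger dispersion and 1097 in the CpG-stratified test. The 11 windows of the CpG-stratified test became 1 to 34 with a sample left out, 106 with the moderated dispersion alone, 7 without the most variable CpG, 2 with read calls thinned and 3 in 5 kb windows. The 4 windows of 100 kb became 1 without CpGs resembling sequence variants. Fewer reads or windows enter some of these settings, and otherwise the cause was not tested, apart from the comparison at the same CpGs. Of the 20 named windows, 2 changed sign at the same CpGs, to 1.37 points on chromosome 7 from 116916001 and 0.765 points on chromosome 5 from 62000001, 16 kept their sign without a call, and all 20 lost their call with limma on log2 ratios.

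With the replicate number as a block 979 windows were called and 4441 reached nominal p. The prior degrees of freedom were infinite in that fit, so the dispersion was treated as known. The numbers do not pair the samples: deviations from the group means correlated at -0.00586 to 0.0111 between same-numbered samples, and 3 of the 6 samples correlated best with their own number. Promoters, gene bodies, gene lists, mitochondrial and unplaced sequence were not run, as no rn6 annotation was used.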

Other observations

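The count of windows at nominal p in the first model over other splits of the samples was planned before the data were examined. All other tests here were chosen after results had been seen. Across the hypothalamic samples, 69.4% of the 1425026 tested windows were at 80% methylation or more with all samples pooled, and 1.60% were at 10% or less, of which 77.5% had 30 or more CpGs. Runs of 5 or more adjacent windows at 10% or less numbered 245, a pattern known as methylation valleys, and 19 reached 10 kb. The longest were on chromosome 10 from 84116001 to 84136000 (20 kb, 688 CpGs) and on chromosome 12 from 9453001 to 9472000 (19 kb, 575 CpGs). Over the CpGs covered in all samples the runs averaged 2.56% ± 0.0766 in AMC samples and 2.89% ± 0.128 in controls (SD, n = 3; exact two-sided permutation test, p = 0.1), and 155 of the 245 were lower in the AMC group. Intermediate methylation of 30% to 70% in every sample was seen in 26921 of the 558856 windows with 30 or more read calls per sample, and 1332 of these had 30 or more CpGs, a combination that imprinted control regions also show.

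The AMC samples had a lower genome-wide level by read calls, by 3.07 points. Incomplete conversion in the control libraries would add most where least is methylated, yet in windows with 60 or more CpGs the controls exceeded the AMC samples by 0.265 points at the same CpGs, which argues against it as the whole cause of the difference by read calls. A slight difference in conversion was not tested as a part of the smaller differences at the same CpGs. Uneven coverage of CpG-dense DNA is a candidate explanation: the difference was -0.598 points once every sample was measured at the same CpGs, and windows with 60 or more CpGs took 2.81% of AMC read calls against 1.43% of control read calls. A genome-wide change with maternal care may still underlie the remainder and cannot be told apart from chance here, with an exact p of 0.3 for the difference at the same CpGs.

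Windows were called lower in AMC samples far more often than higher. Uneven coverage of the CpGs within a window is a candidate explanation for the size and direction of the difference in these windows. In 240 of the 354 that could be compared at the same CpGs (67.8%), less than 1 part in 3 of the difference was left. Another 73 (20.6%) kept 2 parts in 3 or more. With every CpG at its pooled level, coverage alone gave a median difference of -16.4 points in the 359 windows, against -22.8 points measured. Where a CpG was read mostly in 1 group, its pooled level is mostly that group's. Simulated reads with the real coverage gave only 19 calls among unchanged windows in the first model. All 19 were lower in AMC samples, as were 1284 of the 1631 unchanged windows at nominal p. Coverage is not shown to explain all of the direction. At the same CpGs 879 windows at nominal p were still lower and 218 higher in AMC samples. In simulated reads without a group difference, 266 of 494 were lower at the same CpGs. The other splits of the 6 samples gave 782 to 1385 windows at nominal p at the same CpGs, against 1097 for the real one. The number of such windows thus does not set the real split apart, and their direction in the other splits was not counted. A change with maternal care stays open, as untested. Of the 10 splits of the 6 samples, 1 (the real one) gave as many as 359 windows, with 42 the highest of the others, and 1 gave as many as 3504 at nominal p, with 2164 the highest of the others; 10 splits are too few for a share under 0.05. At the same CpGs 2 of the 10 splits gave 11 windows or more, the highest other being 52 for AMC samples 1 and 2 with control sample 2 against the rest (13 without CpGs resembling sequence variants, where the real split gave 8), which may reflect a structure of the samples that was not identified here.

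All 4 windows of 100 kb called at the same CpGs lay on chromosome 5 between 35200001 and 35700000; 1 of the 10 splits (the real one) gave as many, the highest other gave 3, and 10 splits are too few for a share under 0.05. A sequence variant or haplotype that differs between the groups is a candidate explanation: CpGs at 0 in one sample and methylated in another were 7.32 times as frequent as in the flanks, and none of 5126 autosomal regions of the same size with enough covered CpGs had as high a share. The stretch was picked for its group difference in these same methylation values, and the other regions were not. Its rank therefore does not tell a variant from a loss of methylation. Coverage relative to the flanks was 0.634 ± 0.0135 in AMC samples and 0.866 ± 0.0701 in controls (SD, n = 3; exact two-sided permutation test, p = 0.1). The stretch is sparser in CpGs, with 1714 in 500 kb against 13044 in the flanks of 1 Mb each. Windows with under 10 CpGs took 30.3% of AMC read calls and 32.2% of control read calls on average, with overlapping samples. Whether this difference between the libraries lowered the relative coverage was not tested. A shift of methylation over the whole stretch cannot be told apart from a variant. A loss in AMC samples would itself bring CpGs to 0, so leaving such CpGs out had to shrink the difference whatever the cause. The 67.2% of the difference that was left therefore decides nothing. That share met the bound of 2 in 3 written for a shift, but its bootstrap interval, a rule added after the value was seen, runs from 57.2% to 76.7%. The share takes in 970 of the 1714 CpGs with too few reads for the filter (-13.4 points), while over the other 744 the difference went from -6.95 to -3.23 points.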
